A study of Rattus norvegicus with 9 samples.

How the data were processed

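Gene expression was measured in the left ventricle of 9 rats, in tissue taken outside the infarct. Per the labels, total RNA was extracted with Trizol, reverse transcribed, transcribed in vitro into biotin-labelled cRNA and hybridised to Affymetrix Rat Genome 230 2.0 arrays, with 1 rat per array. The groups held 3 rats each: sham-operated rats (numbers 1, 4 and 8), infarcted rats given vehicle (numbers 1, 2 and 4) and infarcted rats given recombinant human neuregulin-1 (rhNRG-1; numbers 2, 3 and 4). The groups are called sham, vehicle and NRG1. The dose, the length of treatment, the time after infarction and the software that made the array values are not given in the sources used here.

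The deposited values are ratios, as read from the values themselves, since no scaling is stated. In the dim probe sets the values checked on each array, those above the floor and up to 20 steps, were whole multiples of 1 step, within 0.1 of a step, as if a whole-number signal had been divided by a constant of that array. For 15942 of the 31042 probe sets the median over the 9 arrays was 1 (within 5e-04), and for 15100 it lay under 1, so the brighter part of the probe sets had also been divided by their own median. Values were floored at 0.01, which on most arrays is no whole multiple of the step. A deposited ratio can therefore be compared between arrays for 1 probe set, but not between bright probe sets, and nothing could be set against a background. The number of arrays limits the precision, and no counting interval applies.

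The step varied between arrays and was divided into 2 ranges at its widest gap on a log scale. It lay between 0.0101 and 0.0119 in sham 1, 4 and 8 and vehicle 2 and was 0.0100 in vehicle 1, which are called the coarse-step arrays. It lay between 0.00595 and 0.00714 in vehicle 4 and NRG1 2, 3 and 4, the fine-step arrays. This division is called the array-scale batch. No label names a batch, so the division was read from the values alone, and its cause is not known. Sham and NRG1 shared no batch, so a fit with the batch as a block took vehicle minus sham from 3 sham and 2 vehicle arrays, NRG1 minus vehicle from the 3 NRG1 arrays and vehicle 4 alone, and NRG1 minus sham as the sum of both. These are the within-batch values.

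Ratios were transformed to log2 without a pseudocount. Probe sets whose median over the 9 arrays was above the 40th percentile (0.725) were kept, which left 18608 probe sets. The medians of the 15942 probe sets divided by their own median ranged from 0.827 to 1.154 between arrays, so the kept values were quantile normalized. Group means were fitted to all 9 arrays at once with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the kept probe sets, and probe sets with an adjusted p under 0.05 were called. Differences among the 3 groups were tested with the moderated F statistic of the same fit. The moderation had 2.29 prior and 6 residual degrees of freedom.

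The plan written before the data were examined assumed signals. It named log2 after adding a constant in signal units, a filter on the mean log2, and moderation with an intensity trend. The constants do not suit ratios, a mean log2 of values divided by their own median removes genes that fell, and such values carry no intensity. The constant was dropped, the median replaced the mean, and the trend was left out, before any calls were seen.

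Symbols came from the platform's annotation, updated through the annotation of assembly GRCr8 (used only for names and for which genes are neighbours). Of the probe sets, 20826 had 1 symbol, 436 had several and 9780 had none. Of the symbols, 20758 were matched by gene identifier, 2 by accession and 66 were kept from the platform. A gene (10669 kept) was represented by its kept probe set with the highest median, with ties broken by the type of probe set and then the identifier. Lists of genes fixed before the data were examined (38, of which 37 had at least 3 kept members) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists of a comparison. Camera with the correlation estimated for each list and limma's fry were run beside it. A list is described by the median log2 difference of its members.

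Named genes followed a rule fixed beforehand. It takes up to 12 called genes in each direction with the largest fold and no overlap between groups, or the 5 with the smallest unadjusted p in each direction where none was called. It adds up to 4 members with the smallest unadjusted p of each described list, and Nppa, Nppb, Myh6, Myh7, Atp2a2, Nrg1, Erbb2, Erbb3, Erbb4 and Mylk3. Similarity of the arrays was tested by an exact permutation of the 280 groupings into 3 groups of 3, on the mean distance between minus within groups.

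The procedure was tested on simulated data with 18608 probe sets, of which 67 were changed 2-fold, 67 4-fold and 66 8-fold in each comparison. For vehicle minus sham, 4.48% of 2-fold, 37.3% of 4-fold and 57.6% of 8-fold changes were called, with 2 false calls. For NRG1 minus vehicle the shares were 5.97%, 43.3% and 71.2%, with 3 false calls. For NRG1 minus sham they were 1.49%, 41.8% and 66.7%, with 7 false calls. Lists of 48, 34 and 19 genes shifted by 0.5 log2 among 10669 genes in vehicle minus sham were recovered with adjusted p = 7.74e-06, 6.63e-26 and 1.98e-07, and with adjusted p = 0.0277, 0.000578 and 0.0266 with an estimated correlation. No other list was called. The simulated genes varied independently of each other, while in the real arrays the estimated correlations of these lists were 0.41, 0.29 and 0.07. The simulation therefore does not show how often camera at the preset correlation calls lists of correlated genes falsely. A simulated shift of the fine-step arrays entered the comparisons with slopes of 0.337, 0.664 and 1 in 18608 probe sets, and the block lowered them to 0.00151, -0.00597 and -0.00445.

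Alternatives changed 1 choice at a time, except that values as deposited with no filter, and a trend with robust moderation, changed a pair of choices together: the scaling between arrays, the pseudocount, the filter, the moderation, array weights, the groups in the fit, a block for the rat number or for the array-scale batch, the test of lists, the representative of a gene, and each array left out in turn. Every column of the table was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.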

Results

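Expression was measured with 9 arrays, 1 per rat, in left ventricle outside the infarct, from 3 sham-operated rats, 3 infarcted rats given vehicle and 3 infarcted rats given recombinant human neuregulin-1 (rhNRG-1), a growth factor that acts on cardiac muscle through ErbB receptor kinases. Differences below are in log2 of the deposited ratio after quantile normalization, each with its standard error (SE) from the fit of all 9 arrays, and n = 3 rats per group. Adjusted p values are from limma, and from limma's camera for lists of genes. The number of arrays limits the precision of every value. A value marked within batch compares only arrays of the same scale (coarse step: sham 1, 4 and 8, vehicle 1 and 2; fine step: vehicle 4, NRG1 2, 3 and 4).

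The 3 sham arrays lay together on the first and second principal components, and vehicle 4 lay beside the 3 NRG1 arrays, away from vehicle 1 and 2. The components held 22.5% and 15.2% of the variance. Over the 18608 kept probe sets the mean correlation across genes of vehicle 4 with the NRG1 arrays was 0.0371, and with vehicle 1 and 2 it was -0.184 (values centred on each probe set's mean; genes are not independent replicates). Arrays of different groups were farther apart than arrays of the same group by 0.0855 log2 root mean square, the largest value of the 280 groupings (exact permutation test, one-sided p = 0.00357, the smallest this design allows). The division by array scale gave 0.0994, and the permutation took no account of that scale.

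**Figure D1:**
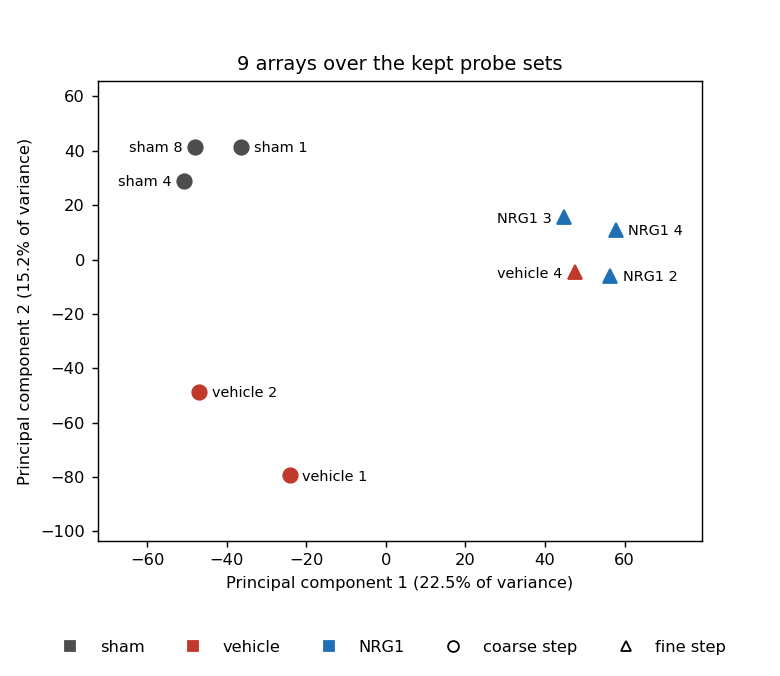
Principal components 1 (22.5% of variance) and 2 (15.2%) of the 9 arrays over 18608 kept probe sets; colours are groups, circles coarse-step and triangles fine-step arrays. Vehicle 4 sits with the 3 NRG1 arrays at the right and the other vehicle arrays sit at the lower left.

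The comparison of vehicle with sham rats asks how infarction altered the ventricle outside the infarct. Genes of energy metabolism fell and genes of the extracellular matrix rose as groups: the complex I list had a median of -0.31 (34 genes, camera adjusted p = 4.62e-06) and the matrix list a median of 0.55 (48 genes, adjusted p = 1.25e-05). Both had adjusted p = 0.386 with an estimated correlation. Nppa, which encodes atrial natriuretic peptide, was higher by 1.83 ± 0.33 (SE, n = 3 per group; 2.01 within batch) on all 3 vehicle arrays without passing the test (adjusted p = 0.264). The ratio of Nppa was 1.13 ± 0.315 (SD, n = 3) in vehicle and 0.29 ± 0.107 (SD, n = 3) in sham rats. Of single probe sets 1 passed limma's test, which has no gene symbol and rose by 3.99 ± 0.32 (adjusted p = 0.0229; within batch 3.88, adjusted p = 0.0338).

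All 6 lists of energy metabolism fell in vehicle rats. Medians were -0.31 for respiratory chain complex I, -0.35 for complexes II to IV (30 genes, adjusted p = 4.62e-06), -0.34 for ATP synthase (14 genes, adjusted p = 0.000631), -0.35 for pyruvate dehydrogenase and the tricarboxylic acid cycle (29 genes, adjusted p = 1.25e-05), -0.30 for fatty acid oxidation (33 genes, adjusted p = 0.000113) and -0.44 for glycolysis and glucose uptake (24 genes, adjusted p = 0.000239). Each had adjusted p = 0.386 with an estimated correlation. Within batch the medians were -0.22, -0.25, -0.13, -0.25, -0.29 and -0.27 in the same order, and all of these lists but ATP synthase (adjusted p = 0.0969) passed there at the preset correlation. With an estimated correlation none of the 12 lists called within batch in this comparison was called (adjusted p from 0.589 to 0.616). The ATP synthase call was also lost without vehicle 4 (adjusted p = 0.102). Of the complex I genes 32 of 34 were lower and 16 were lower on all 3 vehicle arrays than on any sham array. No member of the 6 lists passed over all genes, and 0 passed when adjusted over the list alone. Cs, the citrate synthase gene, differed by -0.84 ± 0.24 (adjusted p = 0.376; -0.76 within batch) and had the same sign in all 4 of its kept probe sets. Slc2a4, which encodes the insulin-dependent glucose transporter, differed by -0.99 ± 0.23 (adjusted p = 0.296; -0.90 within batch) and Pfkm, the muscle phosphofructokinase gene, by -0.76 ± 0.22 (-0.79 within batch). Cd36, a fatty acid transporter gene, differed by -1.61 ± 0.54 (-1.26 within batch) and Sdha, a subunit of complex II, by -0.67 ± 0.21 (-0.61 within batch). Cpt1a, a carnitine palmitoyltransferase gene, differed by -1.18 ± 0.33 (-0.88 within batch), and its other kept probe set had the opposite sign.

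Lists of connective tissue rose. Of the matrix list (0.55) 39 of 48 genes were higher. Within batch its median was 0.25 (adjusted p = 0.0135, and 0.616 with an estimated correlation) and its mean 0.37, less than 2 SE between arrays (0.213) from 0. The fibroblast and myofibroblast list, which shares genes with it, rose with a median of 0.52 (24 genes, adjusted p = 0.000113; within batch 0.22, adjusted p = 0.0257) and had adjusted p = 0.386 with an estimated correlation. The TGF beta and BMP signalling list rose by 0.25 (25 genes, adjusted p = 0.0341), with adjusted p = 0.412 with an estimated correlation. Within batch its median was -0.06 while its test pointed up (adjusted p = 0.55), and the call was lost without sham 4 and without vehicle 4 (adjusted p up to 0.548). Of the matrix and fibroblast lists 0 members passed over all genes or adjusted over the list alone; of the TGF beta list 0 passed over all genes and 1, Bmpr2, adjusted over the list alone. Bmpr2, a BMP receptor gene, differed by 1.24 ± 0.24 (1.26 within batch). Tnc, the tenascin C gene, differed by 1.77 ± 0.46 (adjusted p = 0.355; 1.73 within batch) and Ltbp2, which encodes a protein bound to matrix microfibrils, by 2.96 ± 0.78 (2.37 within batch). Col8a1 differed by 2.75 ± 0.86 (2.47 within batch), Eln (elastin) by 0.99 ± 0.27 (0.87 within batch) and Ccn5 by 3.11 ± 1.02 (2.18 within batch).

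Genes of cardiac muscle moved both ways. The list of fetal and stress genes rose by 0.34 (17 genes, adjusted p = 0.00185; within batch 0.36, adjusted p = 0.00632) and had adjusted p = 0.386 with an estimated correlation. None of its genes passed over all genes and 5 did when adjusted over the list alone. Besides Nppa, Rcan1, which encodes an inhibitor of calcineurin, differed by 1.15 ± 0.30 (1.30 within batch) and Uchl1 by 2.28 ± 0.61 (2.01 within batch). Of the 17 genes 12 were higher and 5 lower. Myh7, also a member of this list, was among the lower ones. Sarcomere and Z-disc genes fell by 0.34 as a list (24 genes, adjusted p = 0.00237), and calcium handling and ion channel genes fell by 0.29 (23 genes, adjusted p = 0.00432). Both lists had adjusted p = 0.386 with an estimated correlation, 0 members that passed over all genes or adjusted over the list alone, and no call within batch (medians -0.20 and -0.30, adjusted p = 0.326 and 0.081) or without vehicle 4 (adjusted p = 0.329 and 0.0837). Ttn, the titin gene, differed by -0.77 ± 0.22 (-0.61 within batch) and Actn2, the Z-disc actinin gene, by -0.56 ± 0.20 (-0.55 within batch). Trdn, the triadin gene, differed by -1.16 ± 0.35 (-1.27 within batch), and 1 of its 4 kept probe sets had the opposite sign. Kcne1, a potassium channel subunit gene, differed by 1.65 ± 0.39 (1.76 within batch). Of the genes set beforehand, Nppb differed by 0.56 ± 0.42, Myh6 by -0.51 ± 0.41, Myh7 by -1.36 ± 0.49, Mylk3 by -0.54 ± 0.34, Erbb2 by 0.07 ± 0.62, and none passed (adjusted p from 0.465 to 0.982). The second kept probe sets of Myh6, Myh7 and Mylk3 had the same sign but other sizes, -2.63 ± 0.92, -0.39 ± 0.25 and -0.68 ± 0.49, and did not pass either (adjusted p from 0.449 to 0.668). Kept probe sets of Atp2a2 and of Nrg1 disagreed in sign, and those of Erbb3 and Erbb4 were too dim to be kept.

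Markers of other cell types moved with the group. Endothelial markers fell by 0.24 (28 genes, adjusted p = 0.0027; within batch -0.38, adjusted p = 0.00632), and the call was lost without sham 1 (adjusted p = 0.0541). Epicardial and mesothelial markers rose by 0.70 (16 genes, adjusted p = 0.00237; within batch 0.75, adjusted p = 0.00942), nerve and glial markers by 0.72 (11 genes, adjusted p = 0.00237; within batch 0.60, adjusted p = 0.00632) and red blood cell markers by 0.85 (6 genes, adjusted p = 0.00853; within batch 0.94, adjusted p = 0.00632), the last lost without sham 8 and without vehicle 2 (adjusted p up to 0.0762). These 4 lists had adjusted p = 0.386 with an estimated correlation. Of their members 0 passed over all genes, and 3 epicardial genes passed adjusted over the list alone. Cav1, the caveolin 1 gene, differed by -2.59 ± 0.64 (-2.06 within batch), Kdr, a VEGF receptor gene, by -0.93 ± 0.26 (-0.99 within batch) and Pecam1 by -0.74 ± 0.25 (-0.75 within batch). Krt8, an epithelial keratin gene, differed by 2.94 ± 0.67 (2.95 within batch), Aldh1a2, which makes retinoic acid, by 1.39 ± 0.26 (1.45 within batch) and Pdpn (podoplanin) by 1.22 ± 0.21 (1.28 within batch). S100b, a glial gene, differed by 1.66 ± 0.50 (1.25 within batch).

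A further 5 lists passed over all 9 arrays but not within batch. Macrophage and monocyte markers rose by 0.24 (30 genes, adjusted p = 0.00853; within batch 0.09, adjusted p = 0.145), with adjusted p = 0.53 with an estimated correlation. Cell cycle genes rose by 0.15 (32 genes, adjusted p = 0.0384; within batch 0.10, adjusted p = 0.0735) and atrial and conduction system markers by 0.45 (11 genes, adjusted p = 0.0341; within batch 0.13, adjusted p = 0.107). Heat shock and protein folding genes fell by 0.31 (28 genes, adjusted p = 0.00991; within batch -0.14, adjusted p = 0.326) and interferon response and antigen presentation genes by 0.53 (31 genes, adjusted p = 0.0161; within batch -0.27, adjusted p = 0.145). The last 4 lists had adjusted p = 0.386 with an estimated correlation. Adjusted over the list alone, 1 cell cycle gene (Gmnn, 1.04 ± 0.22), 2 atrial genes (Nppa and Myl4), 1 heat shock gene (Pdia4, -1.03 ± 0.22) and 0 macrophage or interferon genes passed, against 0 over all genes. Every call among these was lost without vehicle 4, the macrophage, cell cycle and interferon calls also without vehicle 1 and sham 4, the macrophage and cell cycle calls also without sham 1, the atrial call also without sham 1 and sham 4, and the heat shock and interferon calls also without sham 8 (adjusted p up to 0.329). Myl4, an atrial myosin light chain gene, differed by 1.97 ± 0.46 (1.77 within batch), Ifi27, an interferon-induced gene, by -1.02 ± 0.22 (-1.09 within batch) and Ccr1, a chemokine receptor gene, by 0.60 ± 0.23 (0.66 within batch).

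Among genes with a symbol none passed limma's test, and 1786 probe sets had an unadjusted p under 0.05, of which 47.4% were higher. The majority depended on the scaling, with 60.2% higher after median centring and 41.8% in the values as deposited. On all 3 vehicle arrays beyond all 3 sham arrays were 15.7% of the probe sets, where chance gives 10%. The smallest unadjusted p values belonged to Ubn2 (1.85 ± 0.23), Lrp6 (2.11 ± 0.26), Senp1 (2.44 ± 0.32), Rassf10 (2.31 ± 0.30) and Sbsn (2.62 ± 0.37) among higher genes, and to Cebpa (-2.19 ± 0.23), Adam19 (-2.75 ± 0.35), Kcnmb4 (-2.23 ± 0.35), Pmfbp1 (-2.42 ± 0.41) and Arhgap4 (-1.80 ± 0.30) among lower genes, with adjusted p from 0.082 to 0.264. The other kept probe set of Senp1 had the opposite sign. Lrp6 encodes a WNT co-receptor and Cebpa a transcription factor of fat cells. The call of the probe set without a symbol was lost without sham 8 and without NRG1 2, 3 or 4 (adjusted p up to 0.0929), and leaving out vehicle 4 raised the number of called probe sets to 9 and lowered the called lists from 21 to 12. Within batch 2 probe sets were called higher and 7 lower, and 12 lists were called.

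**Figure D2:**
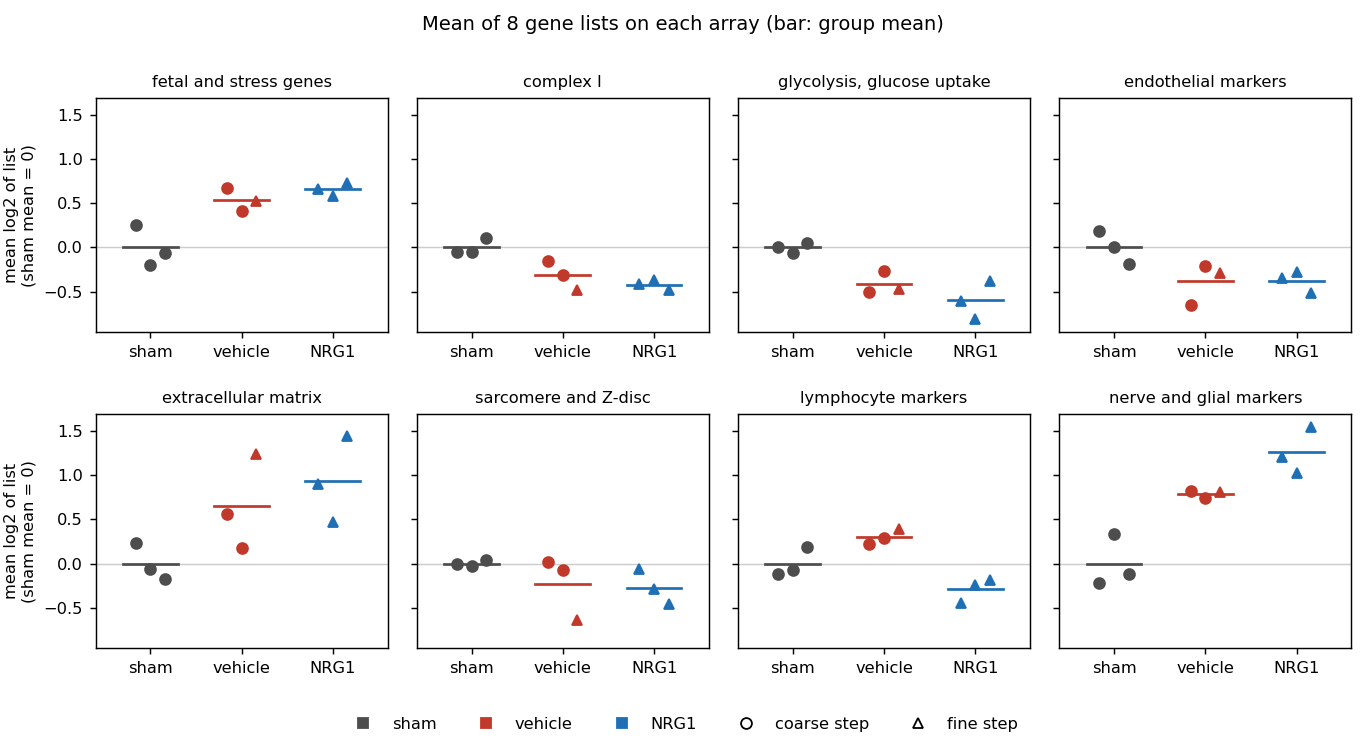
Mean log2 of the members of 8 gene lists on each array, set to 0 at the sham mean; points are arrays (circles coarse step, triangles fine step) and bars group means. The complex I, glycolysis and endothelial lists lie lower in vehicle than in sham rats (vehicle means -0.31, -0.41 and -0.38), and the matrix and nerve lists lie higher (0.66 and 0.79).

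The comparison of NRG1 with vehicle rats asks what rhNRG-1 altered in the infarcted heart. Its within-batch values set 3 NRG1 arrays against vehicle 4 alone, so every within-batch test here assumes that this lone array varies like those of the other groups. Saxo4, a gene for a microtubule-binding protein of cilia, was the only probe set to pass limma's test and fell by 3.84 on the log2 scale (SE 0.28, adjusted p = 0.0093; within batch -3.42). Its ratio lay between 0.0571 and 0.089 on the NRG1 arrays and between 0.852 and 1.174 on the vehicle arrays. Mylk3, which encodes the cardiac kinase of myosin light chain, was higher on all 3 NRG1 arrays by 1.04 ± 0.34 (SE, n = 3 per group; 1.67 within batch), a value that did not pass (adjusted p = 0.487). Its ratio was 1.70 ± 0.489 (SD, n = 3) in NRG1, 0.679 ± 0.0984 (SD, n = 3) in vehicle and 0.997 ± 0.0656 (SD, n = 3) in sham rats. A further probe set of Mylk3 differed by 1.37 ± 0.49. Lymphocyte markers fell by 0.40 as a list (19 genes, camera adjusted p = 0.00274; within batch -0.59), with adjusted p = 0.187 with an estimated correlation, and this call was lost without NRG1 2 (adjusted p = 0.0626).

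Lymphocyte markers were lower for 16 of 19 genes, and 0 passed over all genes or adjusted over the list alone. Prf1, the perforin gene of killer lymphocytes, differed by -2.05 ± 0.66 (-2.83 within batch), Cd4 by -2.18 ± 0.75 (-1.61 within batch), Jchain, the joining chain of antibodies, by -2.05 ± 0.71 (-2.22 within batch) and Cd3g by -0.66 ± 0.26 (-0.72 within batch), with adjusted p from 0.487 to 0.502. Interferon response and antigen presentation genes fell by 0.32 (31 genes, adjusted p = 0.0176; within batch -0.12, adjusted p = 0.356), with adjusted p = 0.79 with an estimated correlation, and 0 of them passed by either adjustment, over all genes or adjusted over the list alone. Cd74, the invariant chain of antigen presentation, differed by -0.63 ± 0.19 (-0.77 within batch). Red blood cell markers fell by 0.74 (6 genes, adjusted p = 0.0201; within batch -0.74, adjusted p = 0.294) and epicardial markers by 0.23 (16 genes, adjusted p = 0.0309; within batch -0.39, adjusted p = 0.0907), both with adjusted p = 0.79 with an estimated correlation. Skeletal muscle markers fell by 0.35 (12 genes, adjusted p = 0.0309; within batch -0.01, adjusted p = 0.815), with adjusted p = 0.458 with an estimated correlation. Slc4a1, the anion exchanger of red cells, differed by -1.53 ± 0.43 with another kept probe set of the opposite sign, Krt8 by -1.89 ± 0.67 and Myl1, a fast myosin light chain gene, by -2.16 ± 0.33. Adjusted over the list alone, 1 red blood cell gene, 1 skeletal muscle gene and 0 epicardial genes passed, against 0 over all genes. The interferon and red blood cell calls were lost without vehicle 2 and without NRG1 2, the skeletal muscle call without vehicle 1, vehicle 2, NRG1 2 and NRG1 4, and the epicardial call without vehicle 1, 2 or 4 and NRG1 2 or 3 (adjusted p up to 0.255).

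Complex I genes fell by 0.09 (34 genes, adjusted p = 0.0393) and genes of pyruvate dehydrogenase and the tricarboxylic acid cycle by 0.14 (29 genes, adjusted p = 0.0309), each with adjusted p = 0.993 with an estimated correlation. Within batch these medians were 0.13 and 0.03 and neither list passed (adjusted p = 0.51 and 0.923). The complex I call was lost without sham 1, 4 or 8, vehicle 1 or 2 and NRG1 2 or 4, and the other call without vehicle 2, NRG1 2 and NRG1 4 (adjusted p up to 0.578). No member of either list passed over all genes, and 0 adjusted over the list alone. Ndufs8 differed by -0.53 ± 0.20 (-0.57 within batch) and Ndufs7 by -0.51 ± 0.21 (-0.48 within batch).

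Lists of cardiac muscle, matrix and neuregulin signalling did not pass over all 9 arrays. The median of the neuregulin and ErbB list was 0.25 (28 genes, adjusted p = 0.224), with 0 genes past the test over all genes and 1 adjusted over the list alone. That gene was Adam19, whose protease is known to cleave neuregulin, with a difference of 2.35 ± 0.35 (adjusted p = 0.185; 2.13 within batch) in both of its probe sets. Erbb2, the receptor partner of neuregulin signalling, differed by 1.37 ± 0.62 (0.86 within batch) and Lrig1, a negative regulator of ErbB receptors, by 1.08 ± 0.29 (0.58 within batch). The sarcomere list had a median of 0.01 and a mean of -0.04 (24 genes, adjusted p = 0.919), and its test pointed down. Myh6, the fast cardiac myosin heavy chain gene, differed by -1.65 ± 0.41 (adjusted p = 0.403; -1.36 within batch), Mef2c by 0.78 ± 0.22 (0.59 within batch) and Xirp1 by 0.93 ± 0.19 (0.81 within batch). The matrix list had a median of 0.28 (48 genes, adjusted p = 0.217). Tnc differed by 1.94 ± 0.46 (1.88 within batch), Cthrc1 by 1.53 ± 0.51 (1.38 within batch), Postn (periostin) by 1.98 ± 0.73 (1.34 within batch) and Mmp2, a matrix protease gene, by -1.44 ± 0.47 (-1.41 within batch), with 1 probe set of Mmp2 of the opposite sign. Nppa differed by -0.02 ± 0.33, Nppb by -0.10 ± 0.42 and Myh7 by 0.56 ± 0.49. The second kept probe sets of Myh6 and Myh7 differed by -2.54 ± 0.92 and 0.24 ± 0.25.

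Against vehicle 4 alone other lists differed, on the assumption that its spread is that of the other arrays. Sarcomere genes differed by 0.34 (adjusted p = 0.00133), fatty acid oxidation genes by 0.26 (adjusted p = 0.0135), heat shock genes by 0.30 (adjusted p = 0.00498) and cytosolic ribosomal protein genes by 0.25 (adjusted p = 0.00731), matrix genes by -0.35 (adjusted p = 0.0336), TGF beta and BMP genes by -0.42 (adjusted p = 0.00203) and fibroblast markers by -0.40 (adjusted p = 0.035). With an estimated correlation none was called within batch (adjusted p from 0.324 to 0.821), and over all 9 arrays none of these 7 lists passed. Of single probe sets 11 were called higher and 1, Saxo4, lower within batch. Levels on vehicle 4 were checked only for those higher probe sets that have a gene symbol. All of these belong to genes at least 2 log2 lower on vehicle 4 than on the other 8 arrays, so their calls rest on that array. Named after their values were seen, they were Tm9sf3, Ptpn12, Nsrp1, Ankrd17, RT1-Ba, S100a14, RT1-Bb, Tmed5 and Cnot6.

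By limma, 1691 probe sets had an unadjusted p under 0.05, of which 51.2% were higher. On all 3 NRG1 arrays beyond all 3 vehicle arrays lay 16.3% of probe sets, where chance gives 10% if arrays are interchangeable. They are not, since all NRG1 arrays were fine-step and vehicle 1 and 2 coarse-step. A shift between the scales alone can raise this share, so it cannot tell group from array scale. In the values as deposited, before normalization, 88.5% of such probe sets were higher and the median of all genes was 0.40, so directions hold relative to the other genes of an array. The Saxo4 call was lost without vehicle 1 and without NRG1 2, 3 or 4 (adjusted p up to 0.127), and leaving out vehicle 4 raised the called probe sets to 7 and the called lists to 11, while leaving out NRG1 2 lowered the lists to 0.

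**Figure D3:**
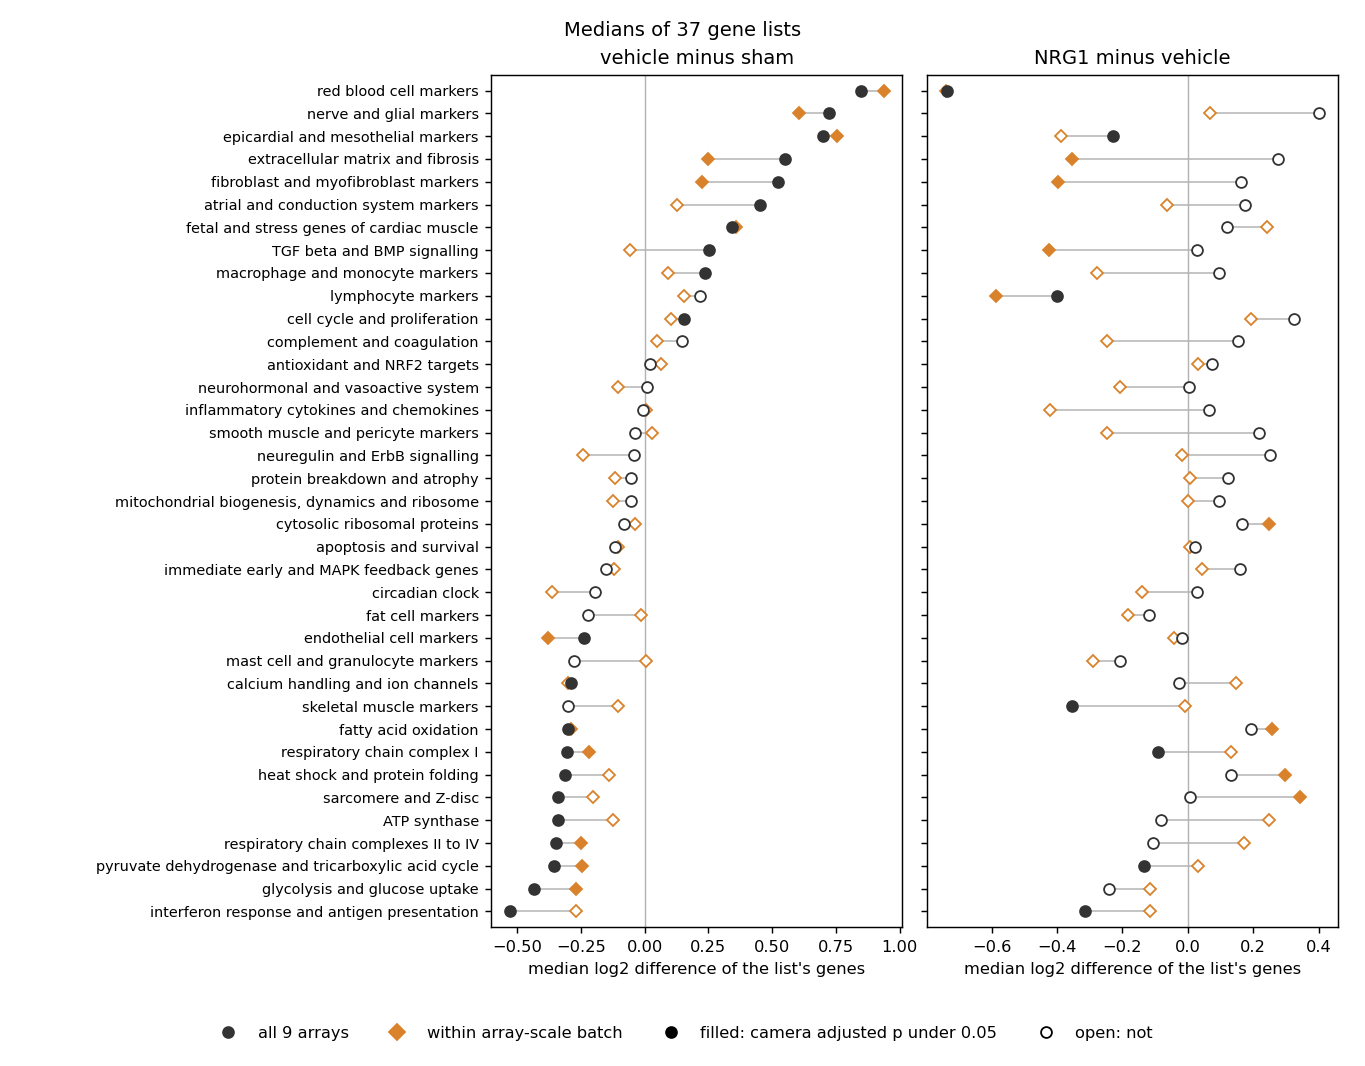
Median log2 difference of each of 37 gene lists over all 9 arrays and within batch, for vehicle minus sham (left) and NRG1 minus vehicle (right). For NRG1 minus vehicle the sarcomere list moves from 0.01 to 0.34 and the matrix list from 0.28 to -0.35 within batch.

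The comparison of NRG1 with sham rats asks what set hearts of treated infarcted rats apart from those of sham-operated rats. Its within-batch values pass through vehicle 4 alone, under the same assumption on its spread. Tnc, the matrix gene tenascin C, rose by 3.71 ± 0.46 (SE, n = 3 per group; adjusted p = 0.0435; 3.61 within batch) and Sbsn, the suprabasin gene of epithelia, by 4.07 ± 0.37 (adjusted p = 0.0144; 3.27 within batch). Saxo4 fell by 4.13 (SE 0.28, adjusted p = 0.00527; -3.49 within batch) and Krtdap, a keratinocyte gene, by 3.10 (SE 0.38, adjusted p = 0.0435; -2.60 within batch). The energy metabolism lists fell and the matrix list rose, as medians of -0.39 for complex I (34 genes, adjusted p = 2.02e-08) and 0.81 for matrix (48 genes, adjusted p = 2.25e-06). These had adjusted p = 0.288 and 0.494 with an estimated correlation, and no call within batch (-0.12 and -0.16, adjusted p = 0.32 and 0.909).

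Of single probe sets 13 rose and 3 fell by limma's test, and 3089 had an unadjusted p under 0.05, of which 54.5% were higher. With median centring this share was 66.2% and in the values as deposited 82.4%. Beyond all 3 sham arrays on all 3 NRG1 arrays lay 26.6% of the probe sets, where chance gives 10%. All sham arrays were coarse-step and all NRG1 arrays fine-step, so these counts cannot tell group from array scale. Besides Tnc and Sbsn, the named genes that rose were Senp1, a gene for a protease that removes SUMO, by 2.55 ± 0.32, Ubn2, a histone chaperone gene, by 2.00 ± 0.23, Lpar1, a lysophosphatidic acid receptor gene, by 2.00 ± 0.24, G0s2, which encodes an inhibitor of fat breakdown, by 1.99 ± 0.25, and Shb, an adaptor gene of receptor kinases, by 1.72 ± 0.22. All 5 had adjusted p = 0.0435. Within batch they differed by 2.61, 2.25, 1.68, 1.86 and 1.53, and the other kept probe set of Senp1 had the opposite sign. Singled out after their values were seen, 1 probe set each of Slc6a6, the taurine transporter gene, and of Camta1 rose by 2.04 ± 0.19 and 1.79 ± 0.22. Of the probe sets without a symbol, the same one that rose in vehicle rats rose by 3.96 ± 0.32 (adjusted p = 0.012) and another fell by 3.04 on the log2 scale (SE 0.35, adjusted p = 0.0435). Within batch 4 probe sets were called higher and 2 lower, and 0 of the 16 were among them.

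The calls of Tnc, Senp1, Ubn2, Lpar1, G0s2, Shb and Krtdap were each lost when any 1 of the 9 arrays was left out, with adjusted p up to 0.116, 0.144, 0.134, 0.144, 0.124, 0.144 and 0.113. The Sbsn call was lost without sham 1, sham 8 or NRG1 2, 3 or 4 (adjusted p up to 0.0917), and the Saxo4 call without sham 8, NRG1 2 or NRG1 3 (adjusted p up to 0.0764). Of the probe sets without a symbol, the call of the one that rose by 3.96 was lost without sham 8 or NRG1 2, 3 or 4 (adjusted p up to 0.0917), and that of the one that fell without sham 8, vehicle 1, 2 or 4, or NRG1 2, 3 or 4 (adjusted p up to 0.134). With an intensity trend in the moderation 168 probe sets were called, a count that cannot tell group from array scale either.

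**Figure D4:**
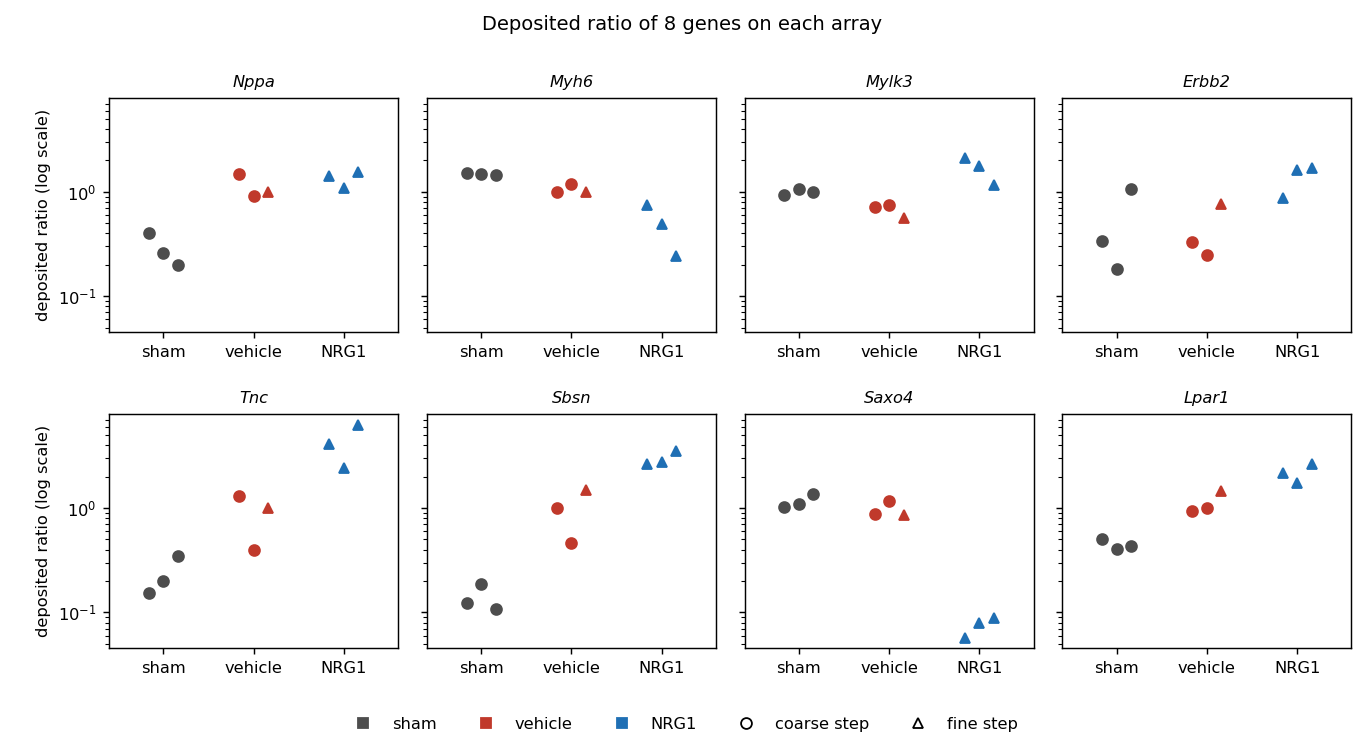
Deposited ratio of 8 genes on each array on a log axis; points are arrays, coloured by group (circles coarse step, triangles fine step). Saxo4 lies between 0.0571 and 0.089 on the NRG1 arrays and at or above 0.852 on the others, and Tnc lies between 2.45 and 6.28 on the NRG1 arrays and at or under 1.30 on the others.

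Energy metabolism lists were lower in NRG1 than in sham rats. Besides complex I, medians were -0.53 for complexes II to IV (30 genes, adjusted p = 1.12e-07), -0.42 for ATP synthase (14 genes, adjusted p = 3.9e-05), -0.42 for pyruvate dehydrogenase and the tricarboxylic acid cycle (29 genes, adjusted p = 2.02e-08), -0.56 for glycolysis and glucose uptake (24 genes, adjusted p = 1.47e-05) and -0.18 for fatty acid oxidation (33 genes, adjusted p = 0.0223). In that order they had adjusted p = 0.288, 0.419, 0.288, 0.266 and 0.69 with an estimated correlation. Within batch their medians were -0.04, 0.13, -0.33, -0.25 and 0.0096, and none passed (adjusted p from 0.082 to 0.909). The fatty acid oxidation call was lost without sham 8 and without NRG1 4 (adjusted p up to 0.34). Over all genes 0 members passed; adjusted over the list alone 7 complex I, 0 complexes II to IV, 1 ATP synthase, 3 tricarboxylic acid cycle, 8 glycolysis (7 lower, 1 higher) and 1 fatty acid oxidation genes did. Slc2a4 differed by -1.64 ± 0.23 (adjusted p = 0.0626; -1.36 within batch), Pfkm by -1.17 ± 0.22 (-1.28 within batch) and Pgam2, a muscle phosphoglycerate mutase gene, by -1.28 ± 0.24 (-0.70 within batch). Cs differed by -1.09 ± 0.24 (-0.87 within batch), Got1 by -1.61 ± 0.34 (-2.02 within batch), Ndufv2 by -1.21 ± 0.26 (-0.49 within batch) and Atp5mg by -1.11 ± 0.25 (-0.41 within batch). Cpt1a differed by -2.25 ± 0.33 (adjusted p = 0.0626; -1.34 within batch), with 1 of its 2 kept probe sets of the opposite sign.

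Fetal and stress genes rose by 0.58 (17 genes, adjusted p = 0.00205) with adjusted p = 0.288 with an estimated correlation, and were the only list also called within batch (0.60, adjusted p = 0.00901, and 0.901 with an estimated correlation). Of these genes 13 were higher and 4 lower, with Myh7 among the lower ones. Over all genes 0 of them passed, and 7 passed adjusted over the list alone. Nppa differed by 1.81 ± 0.33 (adjusted p = 0.0935; 2.33 within batch), Rcan1 by 1.49 ± 0.30 (1.94 within batch) and Xirp1, a gene of the intercalated disc, by 1.02 ± 0.19 (0.85 within batch). Sarcomere genes fell by 0.23 (24 genes, adjusted p = 0.00958; within batch 0.15, adjusted p = 0.0829) with adjusted p = 0.578 with an estimated correlation. Calcium handling genes fell by 0.39 (23 genes, adjusted p = 0.00958; within batch -0.01, adjusted p = 0.902) with adjusted p = 0.288 with an estimated correlation. Both calls were lost without NRG1 4 (adjusted p up to 0.0756). Adjusted over the list alone 3 sarcomere genes (2 higher, 1 lower) and 0 calcium handling genes passed, against 0 over all genes. Myh6 differed by -2.16 ± 0.41 (adjusted p = 0.0965; -1.73 within batch) and its second kept probe set by -5.17 (adjusted p = 0.0885). Mylk3 differed by 0.50 ± 0.34, Erbb2 by 1.44 ± 0.62, Nppb by 0.46 ± 0.42 and Myh7 by -0.80 ± 0.49, with -0.15 ± 0.25 and 0.69 ± 0.49 in the second kept probe sets of Myh7 and Mylk3.

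Fibroblast markers rose by 0.70 (24 genes, adjusted p = 0.000765; within batch -0.29, adjusted p = 0.909) with adjusted p = 0.494 with an estimated correlation. Over all genes 1 matrix gene, Tnc, and 1 fibroblast gene, Tnc again, passed, against 6 and 5 adjusted over the list alone, of which 1 fibroblast gene was lower. Postn differed by 3.27 ± 0.73 (2.33 within batch), Cthrc1 by 2.67 ± 0.51 (2.44 within batch) and Loxl1, which crosslinks elastin, by 2.19 ± 0.49 (1.02 within batch). Nerve and glial markers rose by 1.42 (11 genes, adjusted p = 0.000952; within batch 1.13, adjusted p = 0.065) with adjusted p = 0.266 with an estimated correlation, with 0 genes over all genes and 5 adjusted over the list alone. Gap43, a gene of growing axons, differed by 2.16 ± 0.37 (1.79 within batch) and S100b by 2.56 ± 0.50 (1.32 within batch). Endothelial markers fell by 0.24 (28 genes, adjusted p = 0.00958; within batch -0.50, adjusted p = 0.082) with adjusted p = 0.419 with an estimated correlation, a call lost without sham 1 and without NRG1 4 (adjusted p up to 0.0934). Cav1 differed by -3.52 ± 0.64 (adjusted p = 0.0917; -1.93 within batch), and 0 endothelial genes passed over all genes and 1 adjusted over the list alone.

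A further 4 lists passed. Interferon response genes fell by 0.54 (31 genes, adjusted p = 1.8e-05; within batch -0.43, adjusted p = 0.103) and skeletal muscle markers fell by 0.31 (12 genes, adjusted p = 0.0237; within batch -0.09 with a test that pointed up, adjusted p = 0.909), both with adjusted p = 0.288 with an estimated correlation. Cell cycle genes rose by 0.58 (32 genes, adjusted p = 0.00953; within batch 0.23, adjusted p = 0.082) with adjusted p = 0.325 with an estimated correlation. Macrophage markers rose by 0.44 (30 genes, adjusted p = 0.0227; within batch -0.23, adjusted p = 0.909) with adjusted p = 0.715 with an estimated correlation. The skeletal muscle call was lost without sham 4, sham 8 and NRG1 3, the cell cycle call without NRG1 4, and the macrophage call without sham 1, sham 4 and NRG1 4 (adjusted p up to 0.314). Adjusted over the list alone 4 interferon, 0 skeletal muscle, 1 cell cycle and 0 macrophage genes passed, against 0 over all genes. Ifi27 differed by -1.48 ± 0.22 (adjusted p = 0.0626; -1.69 within batch), Irf7, a regulator of interferon genes, by -2.31 ± 0.51 (-1.44 within batch), Ccnd2 (cyclin D2) by 1.36 ± 0.38 (1.70 within batch) and Mrc1, a macrophage receptor gene, by 1.09 ± 0.31 (1.40 within batch). By fry 7 of the 37 lists passed in this comparison, and 0 in each of the other comparisons.

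Any difference among the 3 groups was found by limma's F test in 5 probe sets, those of Saxo4 (adjusted p = 0.00794), Sbsn and Slc6a6 (adjusted p = 0.042 each) and the probe sets without a symbol that rose and fell in NRG1 rats (adjusted p = 0.0137 and 0.042). At an unadjusted p under 0.05 the F test gave 2475. By the rule in the study's design text, a change of at least 1.5-fold with an unadjusted p under 0.05 between any pair of groups, 4324 probe sets (23.2%) were selected, where that text gives 1950 genes. These counts are not like for like. The text counts genes and does not state its test, while limma's p on 18608 kept, quantile normalized probe sets was used here. The F test gave 0 probe sets without sham 8, NRG1 2, NRG1 3 or NRG1 4, 2 without vehicle 1, 3 without vehicle 2 and 12 without vehicle 4.

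Whether rhNRG-1 moved genes against the direction of infarction was asked across 18608 probe sets. No probe set was called in both vehicle minus sham and NRG1 minus vehicle. Each comparison had only 1 called probe set, so this says little. Both differences contain the vehicle arrays. Their correlation across genes was -0.349, where 100 simulations without any effect gave -0.498 (genes are not independent replicates). Their covariance was -0.167, close to the -0.174 of those simulations, so the correlations alone do not show a departure from no effect. With different vehicle arrays on each side the mean covariance was 0.0354, from -0.0323 with vehicle 1, -0.0489 with vehicle 2 and 0.188 with vehicle 4 set against sham. In the term with vehicle 4 both differences set fine-step against coarse-step arrays. A shift between the scales would make that term positive without any effect of infarction or rhNRG-1. Without vehicle 4 the mean covariance was -0.0666. With the array-scale batch as a block the sign turned, to -0.0163. Cebpa had mean ratios of 1.29 in sham, 0.282 in vehicle and 0.992 in NRG1 rats, and Adam19 of 1.58, 0.23 and 1.35, values that share the vehicle arrays and passed in neither comparison.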

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

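The alternatives with a pseudocount, the filter on the mean log2, only probe sets divided by their own median, the array-scale batch as a block, and the deposited values without a filter were chosen after seeing the data. The planned filter at the 60th percentile and the planned pseudocounts in signal units were not run, since the deposited ratios do not allow them. Where a cause is not named it was not tested.

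A sign change was counted as a reversal only where the result was called in the main fit or in the alternative. By that rule no named gene reversed in any alternative. Sign changes of genes called in neither, which most named genes were, were not counted. Of 156 named genes of NRG1 minus sham, 11 of them called, 6 lost their call with values as deposited, 9 with no filter, 8 with a pseudocount of 0.1 and 11 with the array-scale batch as a block, and 20 gained one with a trend while 6 lost it. Lists were counted by the same rule, on the direction of the test, and reversed only with the array-scale batch as a block. Lists called in neither fit could also turn, such as ATP synthase for NRG1 minus vehicle (median -0.08, and 0.25 with the block). Among the reversed lists, the medians of sarcomere (NRG1 minus vehicle) and skeletal muscle genes kept their sign. For NRG1 minus vehicle the medians of the reversed lists with the block were 0.34 (sarcomere), -0.35 (matrix), 0.13 (complex I), 0.0322 (tricarboxylic acid cycle) and -0.40 (fibroblast). For NRG1 minus sham they were 0.15 (sarcomere), -0.16 (matrix), 0.0096 (fatty acid oxidation), 0.13 (ATP synthase), -0.23 (macrophage), -0.29 (fibroblast) and -0.09 (skeletal muscle; -0.0941). That block also gave 9, 12 and 6 probe sets for vehicle minus sham, NRG1 minus vehicle and NRG1 minus sham, 2865 by the study's rule, and 12 called lists for vehicle minus sham and 1 for NRG1 minus sham.

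The number of called probe sets for vehicle minus sham (1) became 0 with values as deposited, the filter on the mean log2, only own-median probe sets, a pseudocount of 0.1 or 0.32, a trend, a trend with robust moderation and only the 2 groups compared, 5 with no filter and 6 with ordinary variances. For NRG1 minus vehicle (1) it became 0 with no filter, the filter on the mean log2, only own-median probe sets, a pseudocount of 0.32, a trend, a trend with robust moderation and only the 2 groups compared, and 2 with ordinary variances. For NRG1 minus sham (16) it became 9 with values as deposited, 3 with no filter, 63 with only own-median probe sets, 4 with a pseudocount of 0.1, 168 with a trend, 165 with a trend and robust moderation, 56 with array weights and 4 with only the 2 groups compared. The F count (5) became 2 with values as deposited, with median centring and with a pseudocount of 0.1, 3 with no filter and with ordinary variances, and 0 with the filter on the mean log2, only own-median probe sets and a pseudocount of 0.32. The study's rule gave 6547 with deposited values and no filter.

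Rat numbers do not pair the arrays: 0 of the 5 same-numbered pairs had a correlation over 0.1. A block for pairing by number gave 0 called probe sets in each comparison and 2662 by the study's rule.

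With an estimated correlation 0 lists were called in each comparison. Fry called 0, 0 and 7 lists. For NRG1 minus vehicle 1 list was called with no filter and 3 with the mean of a gene's probe sets. The covariance of both effects was 2.99 over the 5 probe sets of the F test, against 0.0354 over all, which the array-scale batch as a block turned to -0.0163, a move smaller than the SD over vehicle arrays.

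Leaving out 1 array in turn gave 0 (sham 8) to 9 (vehicle 4) probe sets for vehicle minus sham, 0 (vehicle 1) to 7 (vehicle 4) for NRG1 minus vehicle, 0 (sham 8) to 10 (sham 4) for NRG1 minus sham, 0 (sham 8) to 12 (vehicle 4) for the F test and 3710 (NRG1 2) to 5062 (vehicle 4) by the study's rule. Called lists ranged from 12 (vehicle 4) to 21, from 0 (NRG1 2) to 11 (vehicle 4) and from 11 (NRG1 4) to 17. The similarity of arrays ranged from 0.0545 (NRG1 2) to 0.133 (vehicle 4) and the covariance from -0.0666 (vehicle 4) to 0.113 (vehicle 1). Signal over background limits what can be read from dim probe sets, and the ratios do not give it.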

Other observations

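The tests of the array-scale batch, of vehicle 4 in probe sets chosen without it, of splits that keep the array scale, of simulated noise with longer tails, of the share of cardiac muscle cells and of the scaling of bright probe sets were chosen only after the result was seen, and the other tests before it.

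The circadian clock list was not called for vehicle minus sham (15 genes, 6 positive and 9 negative, median -0.20, camera adjusted p = 0.216). Tef differed by -1.93 ± 0.33 (SE, n = 3 per group; -2.20 within batch) in all 3 of its kept probe sets and Nfil3 by -1.55 ± 0.42 (-1.42 within batch). NRG1 minus vehicle was 1.01 ± 0.33 for Tef and 1.44 ± 0.42 for Nfil3, differences that share the vehicle arrays. Myl1, a fast myosin light chain gene, had mean ratios of 0.927 in sham, 3.71 in vehicle and 0.944 in NRG1 rats. The hour at which tissue was taken is not given in the sources used here.

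Vehicle 4 lay closer to the NRG1 arrays than to vehicle 1 and 2 (mean r 0.0371 against -0.184 across genes). The array-scale batch could be a cause: over the 12434 dim probe sets left out of the fit, vehicle 4 was closer to the arrays of its own scale by 0.0447 (-0.0901 against -0.135), where pairs of arrays had an SD of 0.0290. A wrong label, with vehicle 4 an NRG1-treated rat, was tested by how far it lay on the way from sham and the other vehicle arrays to pairs of NRG1 arrays: its median was 0.665 (0.691, 0.692 and 0.613), while held-out NRG1 arrays lay at 0.698 to 0.741. Against a wrong label, vehicle 4 fell short of all 3 NRG1 arrays in 13 of the 16 probe sets called for NRG1 minus sham, but these were chosen on the NRG1 arrays: in the 16 with the smallest p from sham and 2 NRG1 arrays, the NRG1 array left out fell short of both in 13, 11 and 14, and vehicle 4 in 12, 12 and 14. A wrong label and the batch cannot be told apart, since both would place vehicle 4 there, although its Saxo4 ratio of 0.852 lay with the other vehicle arrays and not with NRG1 (0.0571 to 0.089), in a gene called with vehicle 4 under its given label.

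Energy metabolism lists were lower and the matrix list higher in vehicle than in sham rats. The batch as the whole cause was examined within the coarse-step arrays, 3 sham and 2 vehicle. The complex I median there was -0.22 and its list mean -0.23 (SE of the list mean 0.0905). Camera's adjusted p was 0.00632, lost with an estimated correlation at 0.589, and at 0.386 over all 9 arrays. These values argue only weakly against the batch for complex I. For the matrix list (0.25, SE of the list mean 0.213) the batch stays open. So few arrays decide neither. Endothelial minus fibroblast medians were -0.76 (95% interval over genes -1.48 to -0.48, which treats genes as independent). Within batch they were -0.60 (-1.27 to -0.15). The list means over all 9 arrays lay apart by -1.16 (SE between arrays 0.378). These values argue only against a lower share of cardiac muscle cells that raises markers of all other cells alike. A lower share with unequal changes among the other cells stays open. For a scaling of bright probe sets, ribosomal minus complex I medians were 0.22 (0.06 to 0.37) and within batch 0.18 (0.01 to 0.35). These intervals also treat genes as independent. The list means lay apart by 0.21 (SE between arrays 0.0629). The values argue only against a scaling that lowers both lists alike. That both lists are equally bright was assumed, since the ratios carry no intensity, and 31 of 65 ribosomal genes were measured. A response of the spared muscle to infarction may be a source, a hypothesis that no test here addressed, and a wider change among the cells that rose stays open as well.

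Some genes stood at 2 levels, at least 2 log2 apart, across the rats: 683 genes, of which 525 were low on 1 array alone and 0 high on 1 alone (the filter leaves out genes low on most arrays). RT1-Ba and RT1-Bb, MHC class II genes chosen after their values were seen, were low only on vehicle 4 (ratios 0.0452 and 0.0275). Noise of single arrays could be a source: 20 simulated sets of arrays with a normal spread held 120 to 180 such genes, under the bound set beforehand, but that bound rested on the assumed spread, since with longer tails (t with 3 degrees of freedom, same SD) they held 495 to 546, so noise stays open. Inherited differences between the rats could be another: of 117 pairs of neighbouring genes (at most 5 genes apart by the GRCr8 annotation) 9 shared their split, where shuffles gave a mean of 9.05 and up to 22 (permutation test, one-sided p = 0.55), and the bound set beforehand, a share no higher than that of shuffles, was wrong, since a variant that acts on 1 gene leaves its neighbours apart and 9 lies inside the spread of the shuffles, so this stays open. The array-scale batch may add to the pattern: coarse-step arrays had 75.8 and fine-step arrays 36.5 genes low on that array alone, a difference of 39.3 (exact permutation test over 126 divisions, one-sided p = 0.00794).

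With 3 rats against 3 there are 10 splits of the arrays, too few for a share under 0.05. For vehicle minus sham the real split gave 1 probe set and 21 lists, and the highest of the others 0 and 13; 1 split gave as many of each. For NRG1 minus vehicle the real split gave 1 probe set and 7 lists and the highest of the others 3 and 14, with as many in 3 and 6 splits. For NRG1 minus sham it gave 16 probe sets and 17 lists and the highest of the others 1 and 10, with as many in 1 split each. The real split of that comparison is also the division by array scale, so these counts cannot tell group from scale. For the 3 groups, the real split gave an F count of 5, with 4 the highest other. By the study's rule it gave 4324, with 3892 the highest other. Each count was reached by 1 of 100 splits of the 9 arrays, the real split included. The 100 were a part of the 280 groupings. Those splits take no account of the array scale, whose own division set the arrays farther apart than the groups did (0.0994 against 0.0855). Of the 40 splits that keep each scale's number of arrays per group, 1, the real one, gave as many by either count, and the highest of the others gave 4 and 4107. The split with 4107 was not among the 100. The F count fell to 0 without sham 8, NRG1 2, NRG1 3 or NRG1 4, to 2 without vehicle 1 and to 3 without vehicle 2, and was 12 without vehicle 4. With 5 against 4 and this dependence on single arrays, chance stays open as a source of the F count.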
